A study of Drosophila melanogaster with 4 samples.

How the data were processed

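ChIP-seq profiles of POF were obtained from head nuclei of mixed adult wild-type Oregon-R flies, per the labels' protocols. Tissue was treated with formaldehyde, nuclei were lysed with detergent and sonication, and chromatin was precipitated with an antibody against POF. The 4 libraries fall into 2 ChIP and 2 input samples by their titles. The labels do not say whether the replicates came from separate fly cultures, so the spread between them may be technical. Values of the input libraries were not analysed here. The read aligner Bowtie 0.12.7 is named, without its settings, per the submitters' processing notes. The genome was FlyBase release 5, per the file headers. The caller of the clusters, its thresholds and the read filters are not given in the sources used here.

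The authors deposited 1 list of regions for each ChIP replicate and 1 for the whole series, each region with its position and a score. The regions are named as significantly enriched or depleted in the lists, and each input is named as the input of a ChIP list, per the labels. The scale and log base of the score are not given in the sources used here. The score belongs to a region and to its list, and served to describe, rank and filter regions within that list. The only use across lists was a correlation of scores between the replicates. Each ChIP replicate thus has a list of its own. How the replicate set combined the replicates is not stated, and its narrowest cluster, 1001 bases, is shorter than the 1301 bases of either replicate list. Regions marked as depleted (19 in the replicate set and 1 in replicate 1) were kept out of all comparisons. No cluster had the same start and end in both replicates, so the lists are not copies of one another. Depth per library is unknown, and the number and width of clusters may depend on it.

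Chromosome lengths came from the file headers. Coverage is the summed length of the clusters, which do not overlap within a list. The large arms are 2L, 2R, 3L, 3R and X. Heterochromatic (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and unplaced (U) sequence stayed out of the main comparisons because it is rich in repeats. Coverage of chromosome 4 was tested with 10000 circular shifts along the joined major chromosomes, and overlap of replicates with 1000 circular shifts within chromosomes. Medians were compared with 100000 random reassignments of chromosome labels to clusters. Such reassignment treats neighbouring clusters as independent, so its p-values describe single lists. Overlap meant at least 1 shared base. All of this ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

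The code was tested on simulated data. With chromosome 4 covered 4 times as densely as the large arms in 9327 simulated clusters, a ratio of 4.03 was recovered. In 100 simulations with equal density on every chromosome, the shift test gave p under 0.05 in 6.0% of cases. Simulated clusters all had the same width and random positions, and fewer shifts were drawn than for the data. The rate was therefore not measured for lists with broad or crowded clusters such as these.

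The main comparisons, their tests, the gene lists and the rule for named regions were fixed before the data were examined. The rule named, from the replicate-set clusters overlapped in both replicates, the 10 with the highest score and the 5 widest on chromosome 4, and the same on the large arms. It also named members of several gene lists. Planned comparisons of genes, gene features and gene lists were not made: the reference gene table at hand follows Release 6 of the assembly, coordinates cannot be carried between builds here, and no annotation of release 5 was used here. Regions are therefore given by position alone. Alternatives were higher score thresholds, width filters, merging of close clusters, a stricter overlap, each replicate list in place of the replicate set, leaving out the X, and adding heterochromatic and unplaced sequence. Results added after the data were seen were the 20 kb limit and all values that rest on it, the 100 kb windows, the uncovered stretches, the classes by width, the shared top clusters, the counts among the 100, 500 and 1000 highest scores, the correlation of scores and the displacement of the shifts. A further 3 alternatives were chosen after seeing the data: a 2000-base width filter, leaving out clusters of at least 20 kb (in the replicate set and in each replicate list, with and without the sequence under them), and only sequence covered in both replicates.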

Results

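POF, an RNA-binding protein of Drosophila melanogaster named for painting the fourth chromosome, was mapped in this series, which recorded where it sat along the genome of adult heads. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on nuclei from sieved heads of wild-type Oregon-R flies with an antibody against POF. The design held 2 ChIP libraries and 2 input libraries, each input serving as the background of the ChIP library with the same replicate number. What was deposited for each ChIP library was a list of regions of significant enrichment, here called clusters, and another list served the whole series and is here called the replicate set. ChIP replicate 1 had 6572 clusters covering 15.4 Mb, ChIP replicate 2 had 5227 clusters covering 13.3 Mb and the replicate set had 9053 clusters covering 20.5 Mb. Read depth is unknown, so no counting interval was attached to any cluster. Positions are those of FlyBase release 5 of the genome. The comparisons used the 6 major chromosome sequences, that is the large arms 2L, 2R, 3L, 3R and X, and chromosome 4, which carried 6238, 5103 and 8361 of the clusters in replicate 1, replicate 2 and the replicate set.

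The first comparison asked how POF was distributed among the chromosomes. POF clusters covered most of chromosome 4 and a small part of every large arm. On chromosome 4, which is 1.35 Mb long and carries genes such as eyeless and cubitus interruptus, known regulators of eye and wing development, clusters covered 66.5% ± 1.51 of the sequence (SD, n = 2). On the large arms together they covered 10.9% ± 0.996 (SD, n = 2), so that the covered share of chromosome 4 was 6.12 ± 0.421 times that of the large arms (SD, n = 2). The single values were 67.6% in replicate 1 and 65.4% in replicate 2 for chromosome 4, against 11.6% and 10.2% for the large arms. In the replicate set the shares were 74.2% and 15.4%, a ratio of 4.81.

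Among the large arms, 2R had the highest mean covered share, 12.2% ± 1.06, and 3L the lowest, 10.3% ± 1.41 (SD, n = 2). Arm 2R was the highest of the large arms in each of the 3 lists. Arm 3L was not the lowest in replicate 1, where it stood at 11.3% and the X at 10.8%. Differences between large arms were not tested. The X was covered to 10.4% ± 0.624, 2L to 10.9% ± 1.31 and 3R to 10.8% ± 0.622 (SD, n = 2). With 2 replicates an exact permutation test cannot reach p = 0.05, so each list was compared with its own clusters moved around the genome. Among 10000 circular-shift permutations of the clusters along the joined chromosomes, 3 in replicate 1, 4 in replicate 2 and 3 in the replicate set put as much cover on chromosome 4 as observed (one-sided p = 0.00040, 0.00050 and 0.00040). Each of those shifts had displaced the clusters by no more than 32.7 kb, a small part of the length of chromosome 4. Shifted clusters covered on average 12.2%, 10.8% and 16.1% of chromosome 4. These p-values describe single lists, because neighbouring clusters are not independent replicates.

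**Figure D1:**
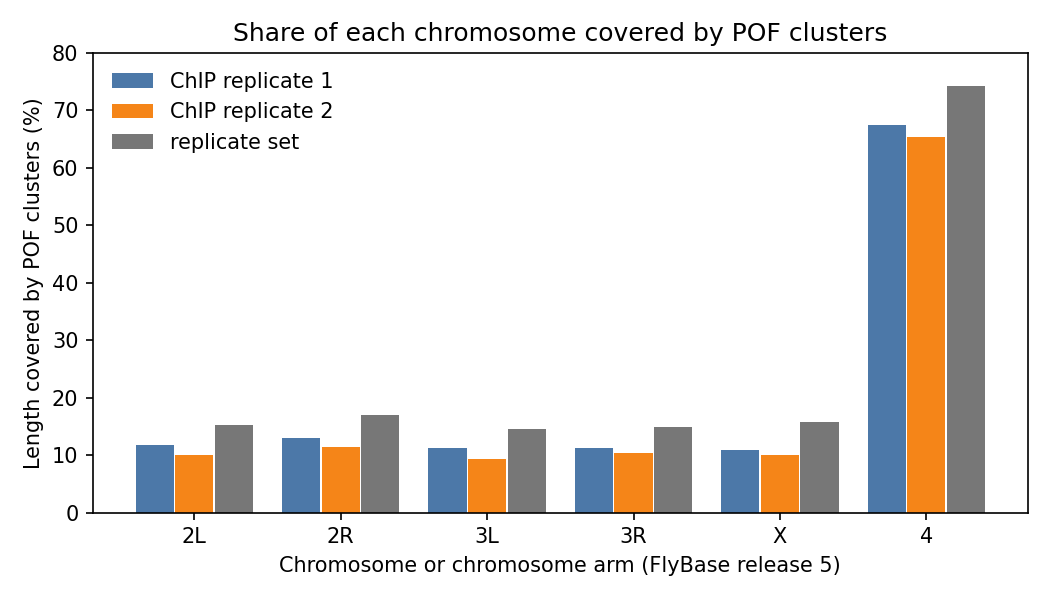
Percent of each chromosome or arm (x axis) covered by POF clusters (y axis), with 1 bar for each ChIP replicate and 1 for the replicate set. Chromosome 4 stands between 65.4% and 74.2%, whereas every large arm lies between 9.31% and 17.1%.

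The excess on chromosome 4 was larger in covered length than in number of clusters. Chromosome 4 held 85 clusters in replicate 1, 75 in replicate 2 and 88 in the replicate set, or 1.36%, 1.47% and 1.05% of all clusters on the major chromosomes, while it makes up 1.12% of their length. The exact 95% binomial interval of the replicate-set share, 0.845% to 1.30%, includes the share of the length. The interval of replicate 1, 1.09% to 1.68%, also includes it, and that of replicate 2, 1.16% to 1.84%, lies just above it. These intervals cover counting error only. By covered length, chromosome 4 took 6.21%, 6.80% and 5.18% of the total in the same lists.

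The second comparison concerned the shape of the clusters. Chromosome 4 held broad blocks, and no large arm had a cluster as wide. Clusters of at least 20 kb, a limit set after the widths were seen, numbered 15 in replicate 1, 15 in replicate 2 and 17 in the replicate set, all of them on chromosome 4, where they spanned 42.8%, 45.6% and 57.7% of the chromosome. The widest block of the replicate set lay at 4: 1022301 to 1106807 and measured 84.5 kb. It was followed by blocks at 187545 to 252509 (65.0 kb), 1222268 to 1279104 (56.8 kb), 872946 to 928262 (55.3 kb) and 263051 to 314974 (51.9 kb). The widest corresponded to 3 narrower clusters in each replicate. The widest single cluster was 68.0 kb in replicate 1 and 61.7 kb in replicate 2. On the large arms the widest cluster reached 13.7 kb in the replicate set, 16.7 kb in replicate 1 and 11.6 kb in replicate 2.

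The median width was 3315 bases on chromosome 4 against 2028 on the large arms in replicate 1. In replicate 2 it was 3003 against 2160 bases, and in the replicate set 2391 against 2005 bases. Permutation tests over clusters (two-sided, 100000 resamples) gave p = 1e-05, 1e-05 and 0.00022, where 1e-05 is the smallest value they can give. These tests treat neighbouring clusters as independent, which they are not, so their p-values describe single lists. Chromosome 4 was also densely covered outside its wide blocks. That rest still held fairly wide clusters. On chromosome 4, 26 clusters in replicate 1, 22 in replicate 2 and 19 in the replicate set reached 10 kb, against 15, 15 and 17 that reached 20 kb. With the blocks and the sequence under them taken out, clusters covered 43.2% of the rest of chromosome 4 in replicate 1, 36.4% in replicate 2 and 39.0% in the replicate set. These shares were 3.73, 3.57 and 2.53 times those of the large arms (one-sided p = 0.00040, 0.00050 and 0.00040 in circular-shift permutations). The difference of median widths without the wide blocks, a removal that touched chromosome 4 alone, was 898, 206 and 111 bases (two-sided permutation p = 1e-05, 0.0072 and 0.190).

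**Figure D2:**
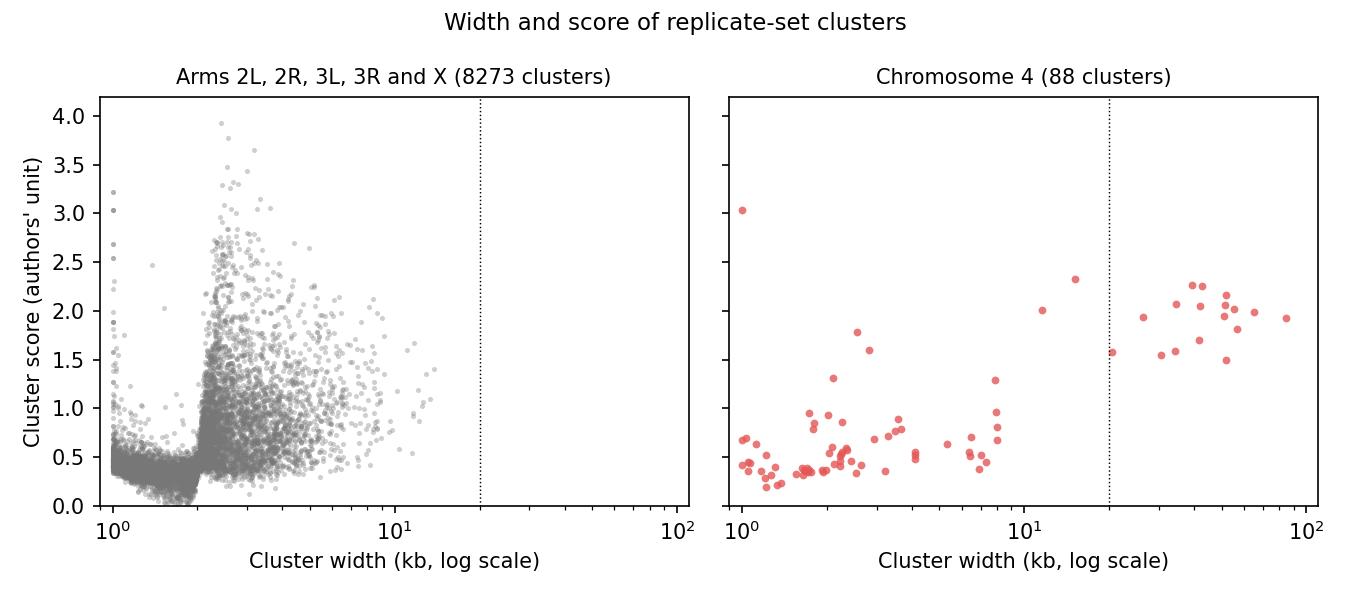
Width of each replicate-set cluster in kb (x axis, log scale) against the score given by the authors (y axis), for the large arms on the left and chromosome 4 on the right; each point is 1 cluster and the dotted line marks 20 kb. The 17 clusters beyond the line are all on chromosome 4, with scores between 1.49 and 2.26, and the 10 highest-scoring large-arm clusters found in both replicates are 2.43 to 3.34 kb wide.

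Chromosome 4 was not covered evenly. Stretches of at least 10 kb with no cluster in any of the 3 lists numbered 7 and added up to 138 kb. They were the first 25.3 kb of the assembled sequence, 538519 to 552498, 720211 to 749263, 752677 to 769161, 834423 to 853735, 857225 to 872945, and 1106808 to 1124728. Windows of 100 kb were used only where complete, which left out chromosome 4 after position 1300000. In that end, replicate 1 had no cluster from 1310864 to 1321515 and from 1335698 to 1346270. Replicate 2 had none from 1310975 to 1321691 and from 1335608 to 1346252. The replicate set had no uncovered stretch of 10 kb there. The lowest window therefore need not be the least covered part of the chromosome. Among complete windows, cover was highest between 200001 and 300000, at 94.9% in replicate 1 and 91.3% in replicate 2. It was lowest between 700001 and 800000, at 26.7% and 27.2%. In the replicate set the same windows stood at 98.1% and 41.8%. Of the 1189 complete windows of the large arms, 54 in replicate 1, 36 in replicate 2 and 12 in the replicate set were covered at least as much as the lowest of the 13 complete chromosome 4 windows, and 0 reached the median of those 13 in any list. Their own median was 10.2% in replicate 1, 9.12% in replicate 2 and 14.2% in the replicate set.

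**Figure D3:**
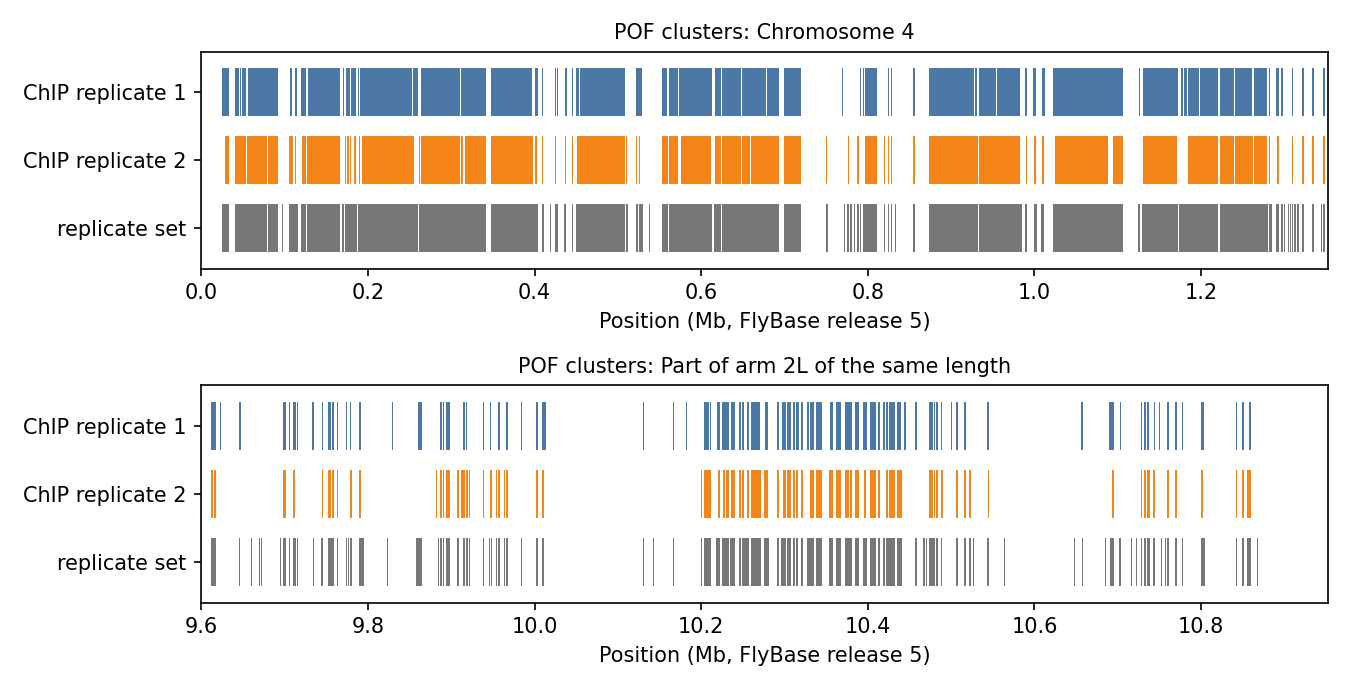
POF clusters drawn to scale along chromosome 4 (top) and along a stretch of arm 2L of equal length (bottom), with position in Mb on the x axis and 1 track for each ChIP replicate and for the replicate set; the 2L stretch was chosen after its values were seen. Filled blocks are clusters. Chromosome 4 shows blocks of up to 84.5 kb in the replicate set, 68.0 kb in replicate 1 and 61.7 kb in replicate 2. Arm 2L shows clusters narrower than these blocks, which crowd between 10.2 and 10.5 Mb.

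The third comparison ranked clusters by the score in the authors' lists, whose scale is not given in the sources used here. Apart from a correlation of scores between the replicates, scores were used only within a list. Among replicate-set clusters of the major chromosomes that were overlapped in both replicates, the highest scores belonged to narrow clusters outside chromosome 4. The top 10 of the large arms scored 3.14 to 3.93 and were 2.43 to 3.34 kb wide. The first of them lay at 3R: 11054022 to 11056450 (score 3.93), followed by 2R: 19252853 to 19255417 (3.77), 3R: 9485019 to 9488188 (3.65), 2R: 16448804 to 16451340 (3.48) and 2L: 10412274 to 10415274 (3.44). The remaining 5 were 2R: 5063736 to 5066410, 3L: 13033095 to 13035879, 3R: 19933680 to 19936126, 2R: 5473180 to 5475790 and 2R: 4837403 to 4840742. Arm 2R held 5 of the 10 sites, 3R 3, 2L and 3L 1 each, and the X 0, which counts clusters and was not tested.

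The top 10 of chromosome 4 scored 1.98 to 2.32 and were 11.6 to 65.0 kb wide. They were led by 795451 to 810630 (score 2.32), 127050 to 166390 (2.26) and 1129725 to 1172424 (2.26). The next were 454293 to 506115 (2.16), 658863 to 693262 (2.07), 560925 to 612529 (2.06), 355948 to 398024 (2.05), 872946 to 928262 (2.02), 80256 to 91819 (2.00) and 187545 to 252509 (1.98).

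Among the 100 highest-scoring clusters of the major chromosomes, 0 in replicate 1, 1 in replicate 2 and 1 in the replicate set lay on chromosome 4, where its share of all clusters would give 1.36, 1.47 and 1.05. Among the 500 highest the numbers were 25, 23 and 21, where its share would give 6.81, 7.35 and 5.26, and among the 1000 highest they were 32, 28 and 24 against 13.6, 14.7 and 10.5. These counts were not tested. The highest chromosome 4 score of the replicate set, 3.03, belonged to a cluster that was not overlapped in both replicates and so is not among the 10 above.

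The median score of chromosome 4 clusters was higher than that of the large arms in replicate 1, at 0.773 against 0.639 (p = 0.00096), and in the replicate set, at 0.585 against 0.464 (p = 0.0022, two-sided permutation tests over clusters, 100000 resamples each). In replicate 2 the medians were 0.797 and 0.747, and the test did not separate them (permutation p = 0.469). As for the widths, these tests treat neighbouring clusters as independent, which they are not. The wide blocks had a median score of 1.82 in replicate 1 and 2.25 in replicate 2, whereas chromosome 4 clusters under 20 kb had medians of 0.728 and 0.701. Without the wide blocks the difference of the medians was 0.0883 in replicate 1, -0.0467 in replicate 2 and 0.0512 in the replicate set (two-sided permutation p = 0.0231, 0.540 and 0.115). That removal touched chromosome 4 alone and took only scores above its median. A fall was therefore built in, and it does not show that scores outside the blocks equal those of the large arms.

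The fourth comparison measured how far the replicates shared clusters. Of the replicate 1 clusters on the major chromosomes, 69.9% were overlapped by a replicate 2 cluster by at least 1 base, and 84.5% of the replicate 2 clusters were overlapped by replicate 1. Circular-shift permutations within chromosomes gave 19.4% and 23.3% on average (one-sided p = 0.0010 each, the smallest value that 1000 shifts can give). The Jaccard index of covered length was 0.616 over the major chromosomes, 0.897 on chromosome 4 and 0.599 on the large arms, with 0.0781, 0.498 and 0.0575 under shifts. On chromosome 4 the Jaccard index exceeded every shift (permutation p = 0.0010). The shares of overlapped clusters there, 85.9% and 90.7%, could not be distinguished from the 82.8% and 84.1% of the shifts (permutation p = 0.249 and 0.0699). In both replicates together, 62.9% of chromosome 4 and 8.16% of the large arms were covered. For the 4277 replicate 1 clusters that overlapped exactly 1 replicate 2 cluster, the scores of the pair had a Pearson r of 0.876 and a Spearman rho of 0.784. These are correlations across clusters, which are not independent replicates. All of the top 20 clusters of the large arms in either replicate were overlapped in the other, and 15 were in both top 20 lists.

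On the large arms, wider clusters recurred more often; the width classes were chosen after the data were seen, and the difference was not tested against the higher chance overlap of wider clusters. Clusters narrower than 2 kb made up 45.9% of the large-arm clusters of replicate 1, and 43.1% of them were overlapped in replicate 2. Those of 2 kb or more were overlapped in 92.3% of cases. In replicate 2 the corresponding shares were 60.1% and 95.4%.

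The replicate set was compared with the single lists to learn what it holds. Replicate-set clusters on the major chromosomes were overlapped by both replicates in 50.3% of cases (exact 95% interval 49.2% to 51.4%), by replicate 1 only in 16.5%, by replicate 2 only in 8.77% and by neither in 24.5%. The 2046 clusters found in neither had a median width of 1188 bases and a median score of 0.405, against 2444 bases and 0.741 for those in both. That width of 1188 bases is below 1301 bases, the narrowest cluster of either replicate list. The share in neither may therefore partly reflect unlike width limits. Clusters overlapped by replicate 1 only or by replicate 2 only had lower median scores, 0.367 and 0.347, than those in neither. On chromosome 4 the share in both replicates was 59.1% (52 of 88 clusters), and those 52 made up 946 kb of the 1003 kb covered.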

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

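The tests in this part were chosen after the result was seen. Clusters also lay on sequence that the comparisons left out. The replicate set had 692 clusters on heterochromatic and unplaced sequence, outside the main comparisons, and no list of a control was used here to set them against. They covered 6.06% of that sequence in the replicate set, 3.58% in replicate 1 (334 clusters) and 1.73% in replicate 2 (124 clusters), each below the large arms. These shares pool unlike sequence. On 2LHet, 2RHet, 3LHet, 3RHet and XHet together they were 8.74%, 5.29% and 2.70%, and on unplaced U 3.81%, 2.12% and 0.929%, in the same order of lists. Both replicates overlapped 12.7% of the 692 clusters (exact 95% interval 10.3% to 15.4%), against 50.2% on the large arms. The 88 clusters found in both had a median score of 1.29 and a median width of 2787 bases, and the 413 found in neither had 0.553 and 1116 bases.

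A candidate explanation for these clusters is calling from few reads, because ratios of small whole numbers recur. Scores equal in every digit to another score of the list were 2.05 ± 0.0846 times as frequent there as on the large arms (bootstrap SE; 51.4% against 25.1%), but only 1.41 and 1.35 times as frequent in replicates 1 and 2. The explanation needed a factor of at least 2 and few clusters in both replicates. The replicate set meets both, the factor by less than its spread, and the factors of the single lists stay below 2. The second condition cannot decide, because unlike width limits of the lists may also lower the share in both. Clusters there in neither replicate had a median width of 1116 bases, below 1301 bases, the narrowest cluster of either replicate list. The explanation therefore remains open. Reads shared between repeats were not tested, and no biological explanation was tested.

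The replicate set also lists 19 regions as depleted of POF. Their scores lie between -0.155 and -0.00304. Replicate 1 has an enriched cluster over 4 of them, and replicate 2 over 8. None of the 19 lies on chromosome 4, which says little, because chromosome 4 makes up only 1.12% of the length of the major chromosomes. The 1 depleted region of replicate 1 is overlapped by an enriched cluster of replicate 2.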

How the results depend on the processing

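The covered-share ratio of chromosome 4 to the large arms stayed above 1 in all 15 alternatives, from 1.07 to 11.5, and past p = 0.05 of the circular-shift permutations in 14. The exception, 1.07 (circular-shift permutation p = 0.384), left clusters of at least 20 kb out of the replicate set but kept their sequence in the length of chromosome 4. Its fall is built in, since such clusters lie on chromosome 4 alone, and it does not show that the excess ends outside them. The same step gave 2.13 in replicate 1 and 1.94 in replicate 2. With the sequence under these clusters taken out as well, the ratio was 2.53 in the replicate set, 3.73 in replicate 1 and 3.57 in replicate 2 (circular-shift permutation p = 0.00040, 0.00040 and 0.00050). All alternatives without these clusters were chosen after seeing the data. The replicate overlap shares and the Jaccard index stayed above the shifts in every alternative run (65.5% to 84.1%, 80.1% to 84.9%, and 0.562 to 0.658). The share of all clusters on chromosome 4, 1.05%, became 1.34% among the upper 50% of clusters by score, 1.58% among the top 25%, 1.30% without the X and 0.972% with heterochromatic and unplaced sequence. The share of covered length, 5.18%, became 7.62%, 11.6% and 6.34% in the same order for the upper 50%, the top 25% and without the X. With single replicates these shares ranged from 1.36% to 1.47% and from 6.21% to 6.80%. The share of replicate-set clusters found in both replicates, 50.3%, was 48.4% when each replicate had to cover 50% of the cluster, and 80.6% among the upper 50% by score. The difference of median scores, 0.12, was 0.0497 without replicate 1 (permutation p = 0.469) and 0.133 without replicate 2. Without clusters of at least 20 kb it was 0.0512 in the replicate set, 0.0883 in replicate 1 and -0.0467 in replicate 2 (permutation p = 0.115, 0.0231 and 0.540). The difference of median widths, 386 bases, was then 111, 898 and 206 bases (permutation p = 0.190, 1e-05 and 0.0072). Falls in both differences are built in, since this step removes chromosome 4 clusters alone. The width difference was 1254 bases when clusters within 500 bases were merged first (permutation p = 1e-05, the smallest value possible), and 844 to 1287 bases with single replicates. Leaving out the X removes sequence from the total; the cause of the other moves was not tested. The 1000-base filter removed no cluster. Gene-based alternatives were not run, because no release 5 annotation was used here. No paired analysis was possible because the lists used here hold no values of the input libraries. Depth is unknown, so a missing cluster does not show absence of POF.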

Other observations

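Of the tests in this part, the gap shuffling on 2L and the comparisons of arm ends and of replicates were chosen only after the values were seen; the widths on chromosome 4 and the median scores of the X had been seen before their explanations were tested. Outside chromosome 4, POF clusters crowded most densely in 1 place. In all 3 lists the most covered 300 kb of the large arms was 2L: 10200001 to 10500000, with 48.8% covered in replicate 1, 45.3% in replicate 2 and 54.2% in the replicate set. When clusters and gaps were shuffled within each arm, the highest value anywhere on the large arms in 200 shuffles was 32.1%, 33.6% and 36.1%. The interval held 42, 36 and 42 clusters with a widest cluster of 11.7 kb in the replicate set, so it held no block as wide as those on chromosome 4. Its median widths of 2757, 2879 and 2997 bases were above the large-arm medians of 2028, 2160 and 2005 bases. Its median scores of 1.03, 1.40 and 0.986 were above the large-arm medians of 0.639, 0.747 and 0.464. The fifth-ranked site of the large arms, 2L: 10412274 to 10415274, lies inside it. The widest replicate-set clusters of the large arms lay near the centromeric end of 2R: 1549407 to 1563153 (13.7 kb), 1021018 to 1034323 (13.3 kb), 1007850 to 1020785 (12.9 kb) and 1183898 to 1196513 (12.6 kb). The next was X: 14963156 to 14975610 (12.5 kb). In the single lists the widest large-arm cluster lay elsewhere, on the X in replicate 1 (16.7 kb) and on 3R in replicate 2 (11.6 kb).

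The ends of the arms next to the centromere did not behave alike. In the last 1 Mb of the X, covered share was 0.448 times that of the rest of the arm in replicate 1, 0.454 times in replicate 2 and 0.425 times in the replicate set. On 2L and 2R it was 1.25 and 1.41 times that of the rest in replicate 1 but 0.876 and 0.845 times in replicate 2, so its direction differed between the replicates. On 3L it was 0.769 and 0.285 times and on 3R 1.07 and 1.05 times in replicates 1 and 2. Replicate 1 covered 2.07 times as much heterochromatic and unplaced sequence as replicate 2, against 1.14 times on the large arms and 1.03 times on chromosome 4. With 2 libraries an exact test of these ratios cannot reach p = 0.05.

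Broad chromosome 4 clusters might be many narrow clusters that lie close together and are joined by the caller. The median gap between clusters was 1449 bases on chromosome 4 and 5530 bases on the large arms in the replicate set. Joining large-arm clusters across gaps of up to 1449 bases left 0.188% of the large arms in clusters of at least 20 kb, against 57.7% of chromosome 4 without any joining. The 9 joined clusters of that width included 2R: 995933 to 1034323 (38.4 kb) and 2R: 1225285 to 1255715 (30.4 kb). Joining at that gap thus fell far short of the blocks on chromosome 4, while a higher density of narrow sites on chromosome 4 itself stays open, because the lists give no signal inside a cluster.

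Clusters of the X had higher median scores than those of the autosomal arms, by 0.123 ± 0.0132 in replicate 1, 0.105 ± 0.0309 in replicate 2 and 0.0857 ± 0.00692 in the replicate set (SE from a bootstrap of 1 Mb blocks). A higher floor of the score for calls on the X may account for this, which predicts a difference among weak clusters that shrinks among strong ones. At the 10th percentile of the replicate set the X lay 0.0704 ± 0.00748 above the autosomal arms, and at the 95th percentile the difference was -0.122 ± 0.0738. Replicates 1 and 2 gave 0.101 and 0.101 at the 10th and -0.123 and -0.186 at the 95th. The X excess was thus absent among strong clusters, but at the median it was no smaller than at the 10th percentile. Any negative value at the 95th percentile met the criterion set for a floor. A higher floor alone would not place the X lower there, so the test cannot decide for it. A single 1 Mb segment of the X does not carry the difference, since the smallest median difference with each left out in turn was 0.0838. What would raise such a floor was not tested, and no biological explanation was tested, because the design has 1 kind of ChIP sample.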
